A study of Mus musculus with 23 samples.

How the data were processed

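RNA was sequenced from 3 groups of 3 libraries each: villus of mice with functional Eed, sorted Lgr5-positive stem cells (ISC) of mice with intact Eed, and villus of mice lacking Eed in the epithelium. Polyadenylated RNA was made into TruSeq V2 libraries, which do not mark strand, and read as 75 bp single-end reads on an Illumina NextSeq, per the labels' protocols. Villus was frozen directly, whereas ISC were released with EDTA, dissociated enzymatically and sorted for high GFP, so cell type and handling differ together. The sex of the mice may differ along with them, since levels of sex-linked genes differed between villus and ISC. Cre activity and Eed loss likewise differ together between the Eed-null and control mice. The 14 chromatin immunoprecipitation and input libraries of the series were not analysed here.

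The authors' deposited tables, 1 for wild-type villus against ISC and 1 for Eed-null against wild-type villus, hold 1 RPKM value per group and gene. Per the file headers of the first table its values are RPKM, reads scaled by gene length and mapped reads; the second table names no unit, which was inferred from its wild-type villus values, equal to those of the first table divided by 1.16193 (range 1.16192 to 1.16194 over 10353 genes). The 2 tables were therefore normalized separately, and tests were made only within a table. The submitters' processing notes name TopHat2 2.0.6, Cufflinks 2.0.1, Bowtie, Cuffdiff and genome build mm9 without their roles; the annotation is not given in the sources used here. The p-value and q-value of each gene were computed by the authors, per the file headers, and the q-values equal a Benjamini-Hochberg adjustment over the genes with status OK to within 8.02e-05. q is listed as 0 for 1389 genes of the first table and 65 of the second. The fold change column was not used, since 1984 and 1406 of its cells hold no number, and folds are ratios of the deposited RPKM values with no pseudocount.

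Because the tables print no value per library, no model was fitted, no spread between libraries can be given, and the depth per library is unknown. The labels call the 3 libraries of a group biological replicates. A gene was called where its status was OK and the authors' q was at or below 0.05. Each table has 22517 named genes and 1 entry naming no gene, which was left out; 13007 and 12525 named genes were tested. Every tested gene reached at least 0.246 RPKM in its higher group in the first table and 0.351 RPKM in the second. A value of 0 can be a failed estimate: the translation factor gene Eef1a1 is listed at 0 in ISC and Apoa4 at 0 in wild-type villus, each with a status other than OK, so no fold is given against a 0. Among tested genes, 82 in the first table and 42 in the second are listed at 0 in 1 group and at 10 RPKM or more in the other, of which 3 and 0 were called, so a listed 0 may also be a failed estimate in a tested gene. Of the symbols, 20864 are current in a GRCm38 gene table, 1533 are older names and 120 had no match; that table was used for names only. Coordinates are those of the files on build mm9, whose start convention is not stated. Genes sharing a locus entry with another gene made up 17.2% of tested and 8.65% of called genes in the Eed-null comparison, and 17.0% and 12.9% in the other.

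The design, the rule for a call, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, with the exceptions named here. Each comparison names Eed, the 8 genes with the largest difference of log2(RPKM + 1) in each direction among called genes, up to 4 called members of each list, Lgr5, Olfm4, Alpi, Sis and Cdkn2a, and 5 genes per pair of directions called in both comparisons. Other list members, among them Ezh2, Sp5, Cdkn2b, Sesn1, Perp, Fas, Aen, Bbc3, Igf2bp1, Pax8, Nkx6-3, Osr2, Dlk1, Sox9, Soat1, Ang4 and Pnliprp2, were named after their values were seen, as were Xist and 4 Y-linked genes; the labels do not give the sex of the mice. Some genes that the rule would name are not reported here.

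The 33 lists cover epithelial lineages (stem cell, enterocyte, goblet, Paneth, enteroendocrine, tuft, secretory progenitor), PRC2 and PRC1 subunits, proliferation, CDK inhibitors, p53 targets, Hox genes, developmental transcription factors, secreted signals, fetal intestine, stomach, ileum or colon, sterol synthesis, PPAR alpha targets, xenobiotic metabolism, antimicrobial or MHC class II, interferon response, Notch pathway, imprinted, ribosomal protein and housekeeping genes, and leukocytes, mesenchyme, endothelium, nerve or glia, red blood cells and pancreas acinar cells. No red blood cell gene was tested between villus and ISC. Called members were compared with the other tested genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 130 tests. A list's median difference of log2(RPKM + 1) was placed among 10000 random lists matched on mean expression in 20 classes. After the data were seen, lists were also tested separately among genes below and at or above 0.351 RPKM in wild-type villus, for higher calls in Eed-null villus, adjusted over 49 tests. Genes are not independent replicates, so these p-values describe gene sets within these libraries. Overlaps used a two-sided Fisher's exact test over 12098 genes tested in both tables, adjusted over the 4 pairs of directions. Chance values shared through the wild-type villus libraries were simulated in 100 draws from standard errors implied by the deposited p-values; covariances used genes alone in their locus entry, a restriction chosen after the simulation over all genes had been seen. Intervals of shares are exact binomial at 95% and cover counting error only.

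The procedures were tested on simulated data for the Eed-null comparison with 12428 genes: 46% of genes changed by 1 on the log2 scale and 91% of those changed by 2 were called, 2.14% of calls fell on unchanged genes, and 1% of 200 random lists had p at or below 0.05. Noise was drawn and tested with the same standard errors, implied by the deposited p-values, so a low share of false calls was built in. These shares check the procedures and give no error rate for the authors' calls. Alternatives were a q of 0.01 or 0.1, a minimum of 2-fold or of 1 on the log2(RPKM + 1) scale, 1 RPKM or more in a group, another set of adjusted genes, 1 entry per symbol, recentred ratios and a pseudocount of 0.1. Recentring keeps the authors' q and shifts all genes alike by a small amount, so it could hardly change a result. The setting of 1 entry per symbol repeated the main calls and could not change a result. Leaving out libraries, a replicate block and refits on counts or per-library values were not run, as they need values per library. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.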

Results

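RNA sequencing measured gene expression in 3 populations of adult mouse intestinal epithelium, with 3 libraries in each: villus and Lgr5-positive intestinal stem cells (ISC) from mice with functional Eed, and villus from mice lacking Eed in the epithelium. Villus cells are the differentiated absorptive and secretory cells of the gut surface, and ISC are the dividing crypt cells that renew them. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that places the repressive histone mark H3K27me3. Eed-null villus came from mice with floxed Eed and a Villin-driven Cre recombinase, and control villus, called wild-type here, from Cre-negative mice with the same floxed alleles. ISC were sorted by GFP from mice with intact Eed that carried GFP and an inducible Cre under Lgr5. Mice of all 9 RNA libraries had received 1 to 2 mg tamoxifen on 5 days. The authors' deposited tables list 22517 named genes with 1 RPKM value per group, so the spread between the libraries of a group is not printed for any value and the depth of each library is unknown. The authors' q is therefore the only measure of error, and a gene is called here where the authors tested it and listed q at or below 0.05.

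Eed, the targeted gene, was lower in Eed-null villus. It stood at 3.00 RPKM against 9.17 RPKM in wild-type villus, a 3.05-fold difference with q = 6.29e-06 in the authors' deposited table. Its locus runs from 97103163 to 97129486 on chromosome 7 of build mm9, and the value counts reads over the whole gene, including exons outside the floxed part. Among PRC2 subunits, 10 of 11 measured members were tested and Eed alone was called, also when adjusted over the list alone. Ezh2, the catalytic subunit, had 6.26 RPKM in Eed-null and 6.73 RPKM in wild-type villus, with q = 0.915 in the authors' deposited table. In ISC, Eed was 2.27-fold higher than in wild-type villus, at 24.2 against 10.7 RPKM, with q = 8.05e-06 in the authors' deposited table.

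Wild-type villus and ISC differed in most of the genes tested. Villus was higher in enterocyte markers and xenobiotic metabolism genes, whereas ISC was higher in stem cell markers, cell-cycle genes and ribosomal protein genes. Fabp6, the ileal bile acid binding protein, had 1678 RPKM in villus and 1.83 RPKM in ISC, a 918-fold difference in the authors' deposited table. Lgr5, the receptor that marks these stem cells, was 30.1-fold higher in ISC, at 18.3 against 0.607 RPKM in the authors' deposited table. Olfm4, a secreted stem cell marker, was 26.8-fold higher in ISC, at 2939 against 110 RPKM in the same authors' deposited table, which lists q of 0 for all of these genes. Of 13007 genes tested, 3973 were called higher in villus and 4201 higher in ISC.

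The other genes with the largest villus excess were Pmp22, Akp3, Clca6, S100g, Apoc3, Pla2g4c and Enpp3, at 152-fold to 534-fold in the authors' deposited table. Akp3, an intestinal alkaline phosphatase, had 1006 against 4.37 RPKM, and S100g, a calcium-binding protein of the enterocyte, had 2170 against 13.7 RPKM in the authors' deposited table. S100g shares its locus entry with another gene. Among the genes with the largest ISC excess were Egr1, Nr4a1, Gkn3, Thbs1, Fosb, Olfm4 and Cyr61. Egr1, an immediate early transcription factor, had 163 RPKM in ISC and 1.93 RPKM in villus, an 84.6-fold difference in the authors' deposited table. Nr4a1, an orphan nuclear receptor induced by stimuli, had 56.2 against 0.210 RPKM, a 268-fold difference in the authors' deposited table. Only ISC were dissociated enzymatically and sorted, whereas villus was frozen directly, and this treatment runs along with the whole comparison. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty are listed at 0 in ISC and had 6.84, 20.2, 3.80 and 3.17 RPKM in villus in the authors' deposited table. Xist, expressed from the inactive X chromosome and sharing its locus entry with another gene, had 39.5 RPKM in ISC and 5.72 RPKM in villus in the authors' deposited table, so sex-linked genes also differed between the groups. The sex of the mice, which the labels do not give, may therefore differ along with the whole comparison.

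Cell type markers divided between the groups. All 31 tested enterocyte markers were called higher in villus, with the same 31 adjusted over the list alone (adjusted p = 4.31e-15, Fisher's exact test against the other tested genes). The sucrase-isomaltase gene Sis had 1310 RPKM in villus and 15.9 RPKM in ISC, and Alpi, another intestinal alkaline phosphatase, 1146 against 15.8 RPKM in the authors' deposited table. Of 28 intestinal stem cell markers, 27 were called higher in ISC, again with 27 adjusted over the list alone (adjusted p = 1.66e-11, Fisher's exact test). Ascl2, a stem cell transcription factor, was 28.3-fold higher and Igfbp4, a binding protein of insulin-like growth factors, 18.1-fold higher in ISC in the authors' deposited table. Sp5 was the exception, with 9.82 RPKM in villus and 8.05 RPKM in ISC and q = 0.364 in the authors' deposited table. All 35 proliferation genes were called higher in ISC, led by the replication helicase subunits Mcm3 (10.9-fold) and Mcm5 (9.30-fold) of the authors' deposited table, with 35 adjusted over the list alone (adjusted p = 3.91e-16, Fisher's exact test). Ribosomal protein genes were called higher in ISC in 68 of 74 cases, with 68 adjusted over the list alone (adjusted p = 7.25e-25, Fisher's exact test), and Rpl36 had 1375 against 193 RPKM in the authors' deposited table.

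Markers of other epithelial lineages went both ways. All 12 tested Paneth cell markers were called higher in ISC, with 12 adjusted over the list alone (adjusted p = 1.1e-05, Fisher's exact test). The metalloproteinase gene Mmp7 had 321 RPKM in the sorted ISC and 56.3 RPKM in villus in the authors' deposited table. Defensin genes of this list are near-identical copies, so their values may share reads. Tuft cell markers were called higher in villus in 14 of 15 cases, with 14 adjusted over the list alone (adjusted p = 6.04e-06, Fisher's exact test), including Rgs13, a regulator of G protein signalling, at 13.6 against 1.69 RPKM in the authors' deposited table. Goblet cell genes divided, with 8 higher in villus and 4 higher in ISC of 16, and enteroendocrine genes with 5 and 13 of 25. The counts adjusted over the list alone were the same, and neither list passed Fisher's exact test (smallest adjusted p = 0.14). Nts, the hormone neurotensin, was 206-fold higher in villus and Neurog3, the factor that starts the enteroendocrine lineage, was 23.2-fold higher in ISC in the authors' deposited table. T cell and other leukocyte genes were called higher in villus in 13 of 21 cases, 14 adjusted over the list alone (adjusted p = 0.0156, Fisher's exact test), with the granzyme Gzma at 69.6 against 14.2 RPKM in the authors' deposited table. Of 11 tested pancreas acinar genes, 6 were called higher in ISC and 1 when adjusted over the list alone (adjusted p = 0.374, Fisher's exact test), with the colipase gene Clps at 476 against 116 RPKM in the authors' deposited table.

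Xenobiotic metabolism, interferon response and PPAR alpha target lists were enriched among genes higher in villus. All 26 xenobiotic metabolism genes were called higher there, with 26 adjusted over the list alone (adjusted p = 8.31e-13, Fisher's exact test), among them the cytochrome P450 genes Cyp3a11 (86.9-fold) and Cyp3a13 (82.1-fold) of the authors' deposited table. Interferon response genes were called higher in villus in 26 of 27 cases, with 26 adjusted over the list alone (adjusted p = 1.36e-11, Fisher's exact test), and Isg15 had 134 against 1.96 RPKM in the authors' deposited table. PPAR alpha targets were called higher in 16 and lower in 3 of 20 cases (adjusted p = 5.11e-05, Fisher's exact test), with the same counts adjusted over the list alone. Creb3l3, a transcription factor of lipid metabolism, was 50.1-fold higher in villus in the authors' deposited table. Genes of the ileum or colon list were called higher in villus in 11 of 15 cases and in ISC in 3, with the same counts adjusted over the list alone (adjusted p = 0.00423, Fisher's exact test). Among PRC2 subunits, 7 were called higher in ISC and 2 in villus of 11, also when adjusted over the list alone (adjusted p = 0.133 for ISC, Fisher's exact test). Ezh2 was 3.32-fold higher in ISC and Phf1, an accessory subunit, 6.46-fold higher in villus in the authors' deposited table. PRC1 subunits were called higher in ISC in 11 and in villus in 2 of 20 cases, Notch pathway genes in 9 and 1 of 14, and secretory progenitor genes in 8 and 0 of 12. Adjusted over the list alone these counts were the same except for 10 Notch genes, and no such list passed (smallest adjusted p = 0.0717, Fisher's exact test). Notch1 was 16.6-fold higher in ISC in the authors' deposited table.

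Eed-null villus differed from wild-type villus in fewer genes, and higher levels were more frequent than lower ones. Cdkn2a, which encodes the cell-cycle inhibitor p16 and the p53 activator Arf, stood at 143 RPKM in Eed-null and 0.350 RPKM in wild-type villus, a 410-fold difference in the authors' deposited table. Hoxb13, a posterior Hox gene, rose 830-fold from 0.0991 to 82.3 RPKM, and Phlda3, a p53-induced inhibitor of Akt signalling, 292-fold from 0.166 to 48.6 RPKM in the authors' deposited table. Fabp6 and Akp3, both among the most villus-specific genes, fell 5.74-fold and 8.50-fold, to 251 and 102 RPKM in the authors' deposited table. The authors' deposited table lists q of 0 for these 5 genes. Of 12525 genes tested, 989 were called higher and 433 lower in Eed-null villus. The median log2 ratio of 10003 genes at 1 RPKM or more in both groups was -0.10.

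**Figure D1:**
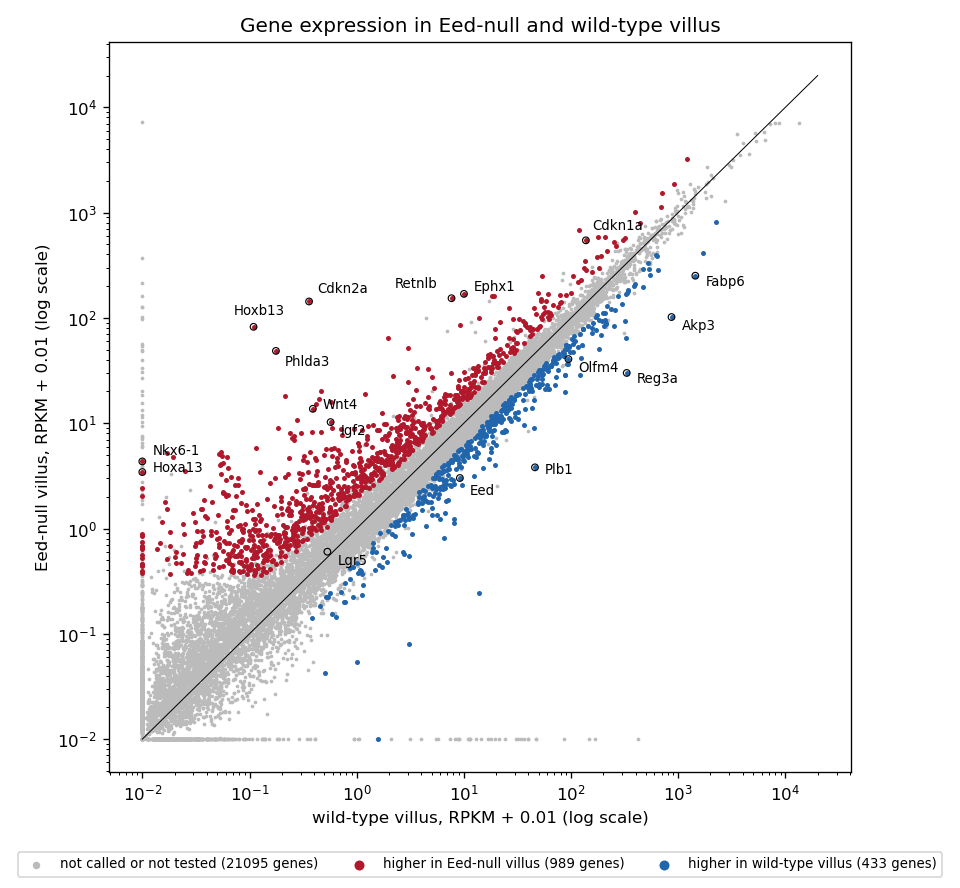
Level of each named gene in Eed-null villus (vertical axis) and wild-type villus (horizontal axis), in RPKM plus 0.01 on log scales, with the 989 genes called higher in red and the 433 called lower in blue; the line marks equal levels. Cdkn2a, Hoxb13 and Phlda3 lie far above the line and Fabp6, Akp3, Reg3a and Plb1 below it.

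The other genes with the largest rise were Akr1b8, Retnlb, Ephx1, Ly6d and Sval1, at 16.9-fold to 44.6-fold in the authors' deposited table. Retnlb, a goblet cell protein with antibacterial activity, rose from 7.66 to 154 RPKM, and Ephx1, a microsomal epoxide hydrolase, rose 16.9-fold to 169 RPKM in the authors' deposited table. The other genes with the largest fall were Trim12a, Reg3a, Plb1, Dnase1, Vwa1 and Ugt2a3. Reg3a, an antibacterial lectin, fell from 331 to 30.0 RPKM, and Plb1, a brush-border phospholipase, 12.1-fold from 46.1 to 3.80 RPKM in the authors' deposited table. Trim12a and Dnase1 each share a locus entry with another gene, and the reads of such genes cannot be assigned with certainty. On build mm9, Cdkn2a lies between 88920376 and 88940523 on chromosome 4, Hoxb13 between 96055674 and 96057913 on chromosome 11, and Phlda3 between 137662661 and 137665711 on chromosome 1.

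p53 target genes rose as a group. Of 20 tested, 17 were called higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 4.68e-15, Fisher's exact test). Gdf15, a stress-induced cytokine, rose 27.9-fold, the kinase gene Plk2 12.8-fold and Ccng1, a cyclin induced by p53, 8.90-fold in the authors' deposited table. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 3.97-fold from 137 to 545 RPKM in the authors' deposited table. Sesn1 was the member called lower, at 31.7 against 52.0 RPKM, and Perp and Fas were not called in the authors' deposited table. Of 6 tested CDK inhibitor genes, Cdkn2a, Cdkn1a and Cdkn1c were called higher and Cdkn1b lower, also when adjusted over the list alone (adjusted p = 0.0355 for the higher direction, Fisher's exact test). Among genes at 0.351 RPKM or more in wild-type villus, which could be called either way, 2 of 5 members were called higher. The list did not pass there (adjusted p = 0.12, Fisher's exact test), but Cdkn2a lies just below that level and is left out. Cdkn2b, the neighbour of Cdkn2a, had 88.8 against 76.9 RPKM, with q = 0.712 in the authors' deposited table. No proliferation gene was called higher, and Mki67 alone of 35 was called lower, with none called when adjusted over the list alone. The median difference of log2(RPKM + 1) of that list was -0.32, at percentile 0.02 of 10000 random lists matched on mean expression, and 32 of 35 members had lower values in Eed-null villus.

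Tested members of the developmental regulator lists were mostly called higher in Eed-null villus, but most members were not tested. Of 39 Hox genes, 15 were tested and 12 called higher, 13 adjusted over the list alone (adjusted p = 2.37e-10, Fisher's exact test). Hoxa10 rose 120-fold from 0.0422 to 5.08 RPKM and Hoxc11 234-fold from 0.0152 to 3.54 RPKM in the authors' deposited table. Hoxa13 had 3.43 RPKM in Eed-null villus and is listed at 0 in wild-type villus in the authors' deposited table. Of 208 developmental transcription factors from other families, 170 were not tested, and of the 38 tested 22 were called higher and 3 lower, 24 and 4 adjusted over the list alone (adjusted p = 7.54e-14, Fisher's exact test). The stomach homeobox gene Barx1 rose 514-fold to 4.79 RPKM, the neural crest gene Pax3 51.3-fold to 1.78 RPKM and Foxf2 58.5-fold to 1.53 RPKM in the authors' deposited table. Nkx6-1, a factor of pancreatic and neural development, had 4.33 RPKM and is listed at 0 in wild-type villus in the authors' deposited table. The members called lower were Pax8, Nkx6-3 and Osr2. Members below 0.351 RPKM in wild-type villus enter these tests only if they are higher in Eed-null villus, which favours higher calls among them. Set only against other tested genes below that level, of which about 50% were called higher, 21 of 23 developmental factors passed (adjusted p = 0.000426, Fisher's exact test). All 15 tested Hox genes lay below it, and their list did not pass there (odds ratio 4.07, adjusted p = 0.129, Fisher's exact test). At or above it, 1 of 15 developmental factors was called higher. Of 17 tested secreted signal genes, 6 were called higher and 1 lower, 7 and 2 adjusted over the list alone (adjusted p = 0.00683, Fisher's exact test), and with 1 RPKM required in a group this list did not pass (adjusted p = 0.0542), nor did it below or above 0.351 RPKM in wild-type villus (adjusted p = 0.32 and 0.347). Wnt4 rose 36.0-fold from 0.380 to 13.7 RPKM, while Bmp3 fell 3.72-fold in the authors' deposited table.

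The fetal intestine list was enriched among genes that rose, and the imprinted list less firmly. Of 15 tested fetal intestine genes, 12 were called higher and none lower, 14 adjusted over the list alone (adjusted p = 2.37e-10, Fisher's exact test). Among genes at 0.351 RPKM or more in wild-type villus 8 of 10 were called higher (adjusted p = 3.58e-08, Fisher's exact test), and with 4 of 5 called the members below that level did not pass against other tested genes below it (adjusted p = 0.741). The RNA-binding protein gene Igf2bp3 rose 30.0-fold from 0.238 to 7.15 RPKM, and Anxa1 40.2-fold from 0.0502 to 2.02 RPKM in the authors' deposited table. Igf2, a fetal growth factor that shares its locus entry with other genes, rose 18.2-fold from 0.561 to 10.2 RPKM in the authors' deposited table. Of 21 tested imprinted genes, 7 were called higher and 1 lower, 8 and 1 adjusted over the list alone (adjusted p = 0.00423, Fisher's exact test). With 1 RPKM required in a group the imprinted list did not pass (adjusted p = 0.0512, Fisher's exact test), nor below or above 0.351 RPKM in wild-type villus (adjusted p = 0.841 and 0.142). Igf2 and Dlk1 are in both lists, and Cdkn1c, Meg3 and Phlda2 were among the others called higher. On the scale of the villus and ISC table, Hoxb13 stood at 95.6 RPKM in Eed-null villus and is listed at 0 in ISC in the authors' deposited tables. The 2 tables were normalized separately, and levels were set side by side through the wild-type villus values they share.

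**Figure D2:**
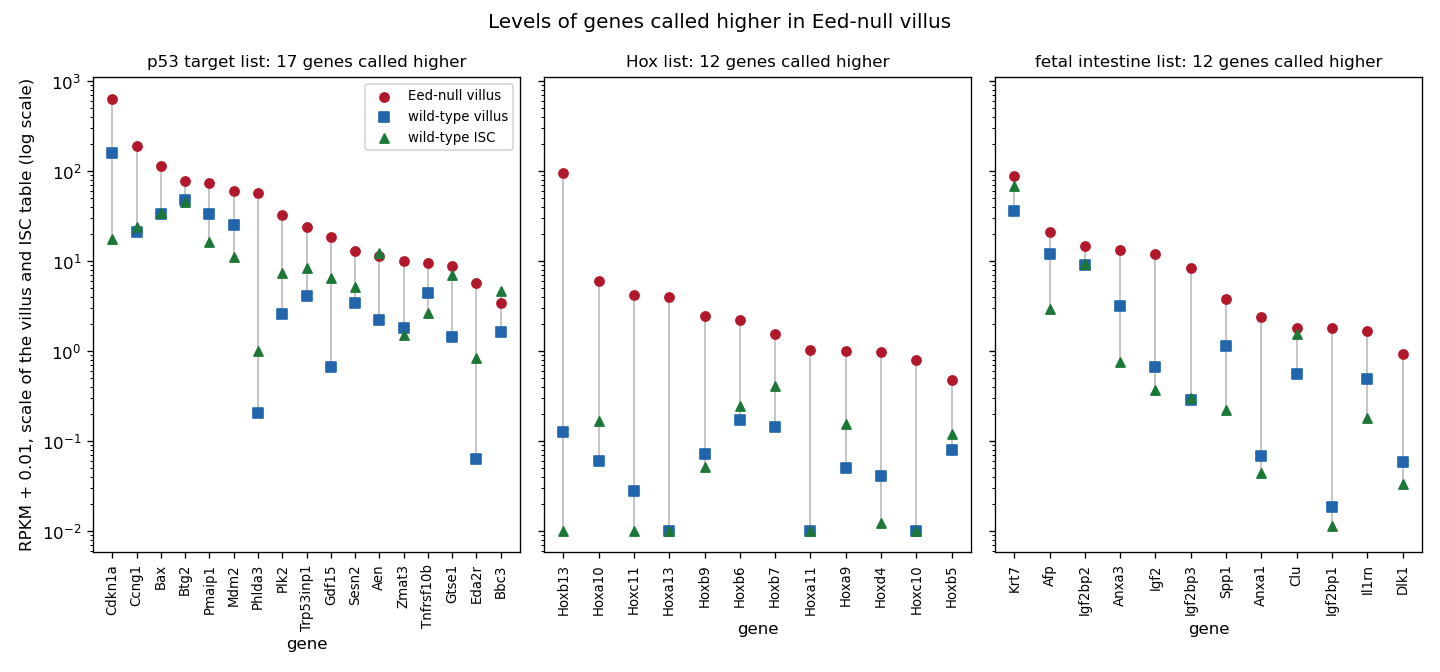
Level of each gene called higher in Eed-null villus, in RPKM plus 0.01 on a log scale, for the p53 target list (17 genes), the Hox list (12 genes) and the fetal intestine list (12 genes); red circles mark Eed-null villus, blue squares wild-type villus and green triangles ISC, and Eed-null values are put on the scale of the villus and ISC table. ISC exceeded Eed-null villus for 2 of the 17 p53 targets, Aen and Bbc3.

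Goblet cell and enteroendocrine lists were enriched among genes that rose, and the xenobiotic metabolism list among genes that fell. Of 16 goblet cell genes, 8 were called higher and none lower, 11 and 1 adjusted over the list alone (adjusted p = 6.92e-05, Fisher's exact test). Fut2, a fucosyltransferase, rose 9.12-fold and Spink4 2.69-fold from 1204 to 3242 RPKM in the authors' deposited table. With a minimum difference of 2-fold the goblet list was no longer enriched (adjusted p = 0.207, Fisher's exact test). Of 24 tested enteroendocrine genes, 6 were called higher and 1 lower, 8 and 1 adjusted over the list alone (adjusted p = 0.0392, Fisher's exact test). The prohormone convertase gene Pcsk1 rose 2.77-fold and Cpe 2.73-fold, while the glucagon gene Gcg fell 3.70-fold in the authors' deposited table. Atoh1, the switch factor of the secretory lineage, rose 1.74-fold and Spdef 1.68-fold in the authors' deposited table, and they were the 2 of 10 secretory progenitor genes called, also when adjusted over the list alone (adjusted p = 0.374, Fisher's exact test). Of 26 xenobiotic metabolism genes, 9 were called lower and 1 higher, 9 and 2 adjusted over the list alone (adjusted p = 1.2e-06, Fisher's exact test). Aldh1a1, a retinaldehyde dehydrogenase, fell 3.39-fold from 319 to 94.1 RPKM, and Cyp3a25 and Cyp2b10 fell 2.46-fold and 2.45-fold in the authors' deposited table.

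Interferon response and sterol synthesis lists were enriched among genes that rose. Of 28 interferon response genes, 13 were called higher and none lower, 17 adjusted over the list alone (adjusted p = 5.68e-07, Fisher's exact test). Ifit2 rose 5.38-fold, Gbp2 4.34-fold and Ifi44 4.08-fold in the authors' deposited table. Of 22 tested sterol synthesis genes, 10 were called higher and none lower, 13 adjusted over the list alone (adjusted p = 1.96e-05, Fisher's exact test). The squalene epoxidase gene Sqle rose 2.10-fold and Pmvk, the phosphomevalonate kinase gene, 2.32-fold in the authors' deposited table, and with a minimum of 2-fold this list was no longer enriched (adjusted p = 0.165, Fisher's exact test). The ileum or colon list went both ways, with 4 called higher and 4 lower of 15, also when adjusted over the list alone. The lower direction was enriched (adjusted p = 0.00683, Fisher's exact test) and the higher was not (adjusted p = 0.0827). Slc37a2 fell 3.75-fold, and Saa1, an acute-phase apolipoprotein, rose 6.97-fold in the authors' deposited table.

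Stem cell, enterocyte and Paneth cell lists were not enriched among called genes in Eed-null villus. The median difference of log2(RPKM + 1) was 0.13 for the stem cell list, at percentile 99.2 of random lists matched on mean expression, and -0.20 for the enterocyte list, at percentile 0.57. Of 24 tested stem cell genes, Cd44, Soat1, Ephb3 and Sox9 were called higher and Olfm4 lower, 5 and 2 adjusted over the list alone (smallest adjusted p = 0.27, Fisher's exact test). Lgr5 had 0.592 RPKM in Eed-null and 0.523 RPKM in wild-type villus, with q = 0.894 in the authors' deposited table. Of 31 tested enterocyte genes, Apoc3, Treh, Ace and Lct were called lower and none higher, also when adjusted over the list alone (adjusted p = 0.0765, Fisher's exact test). Apoc3 fell 2.74-fold from 2243 to 819 RPKM, while Alpi had 633 against 986 RPKM (q = 0.224) and Sis 733 against 1127 RPKM (q = 0.443) in the authors' deposited table. Of 16 tested Paneth cell genes, Ang4, Mptx2 and Pnliprp2 were called higher and Defa20, Defa21 and Defa22 lower, also when adjusted over the list alone (smallest adjusted p = 0.0667, Fisher's exact test). The median level of these 16 genes was 123 RPKM in wild-type villus. Whether crypt cells remained in the villus preparations was not tested. Gzmb, 1.78-fold lower in the authors' deposited table, was the 1 leukocyte gene of 18 called, also when adjusted over the list alone, and 14 of the 18 had lower values in Eed-null villus. Bmi1, Rnf2 and Scmh1, which encode parts of PRC1 or its partners, were the 3 of 20 PRC1 genes called higher, also when adjusted over the list alone (adjusted p = 0.395, Fisher's exact test), with Bmi1 3.68-fold higher in the authors' deposited table.

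**Figure D3:**
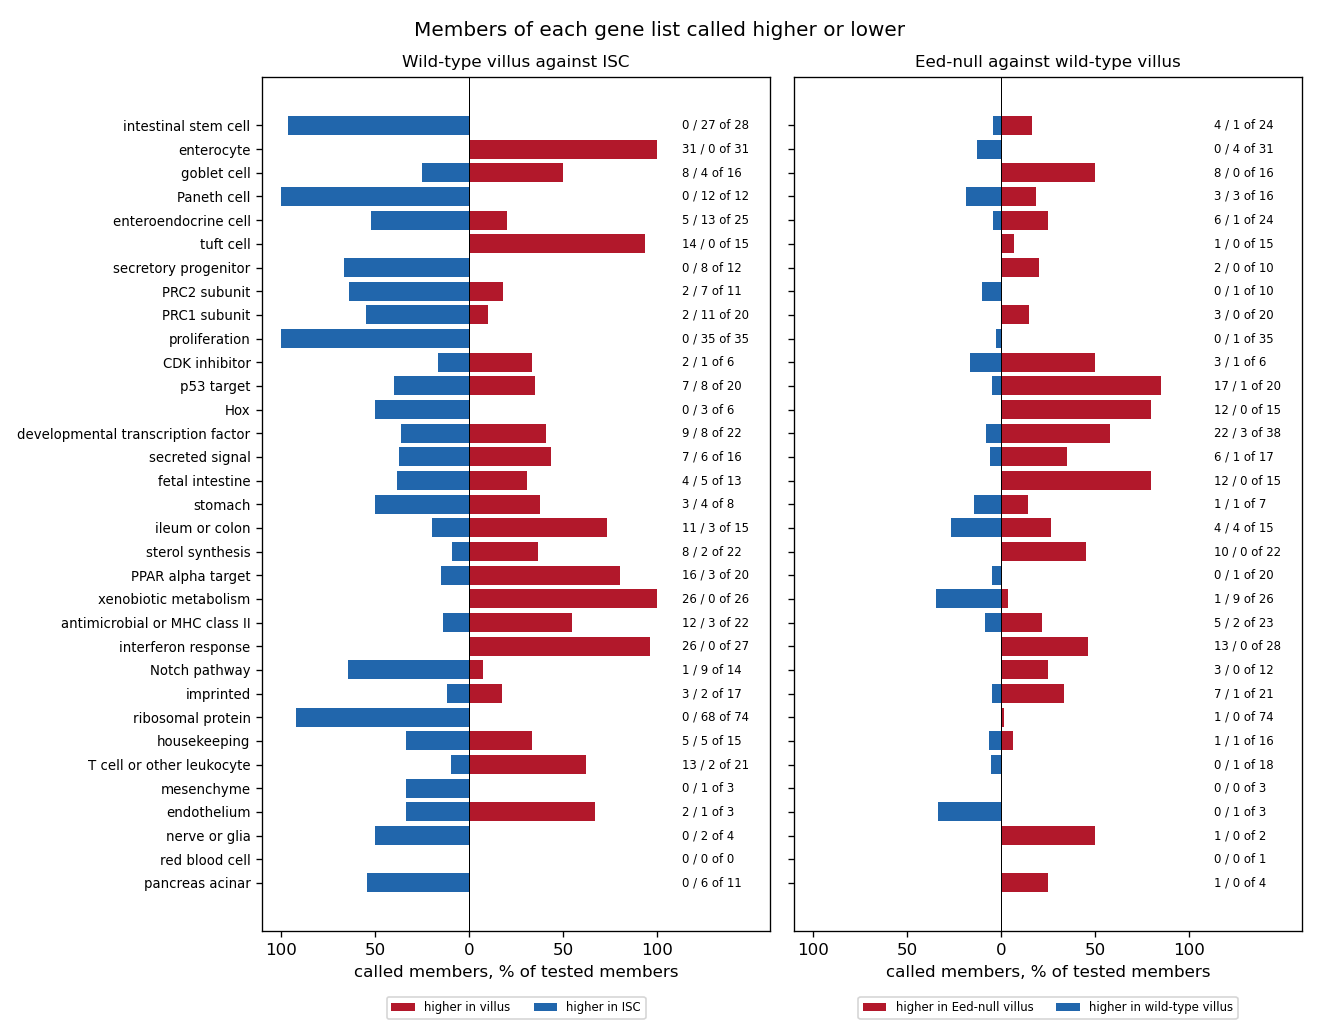
Share of the tested members of each gene list that was called in either direction, for wild-type villus against ISC (left) and Eed-null against wild-type villus (right), in percent of tested members. Numbers at the right of each panel give members called in the red and the blue direction and members tested; the p53 target list has 17 and 1 of 20 in the right panel, and the proliferation list 0 and 35 of 35 in the left panel.

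In the comparisons named here, the remaining lists were not enriched in either direction, though some medians stood apart from random lists matched on mean expression in Eed-null villus. These were antimicrobial or MHC class II genes (18 of 23 tested higher in value, percentile 100), ribosomal protein genes (54 of 74, percentile 99.99), and, with lower values, the leukocyte genes (percentile 0). Medians of the PRC1 list (percentile 99.5) and the secretory progenitor list (99.32) also lay high. In Eed-null villus, 5 antimicrobial or MHC class II genes were called higher and 2 lower of 23 (6 and 2 adjusted over the list alone), 3 of 12 Notch pathway genes higher, and 1 of 15 tuft cell genes higher. PPAR alpha targets had 1 of 20 lower (none adjusted over the list alone), ribosomal protein genes 1 of 74 higher (none adjusted over the list alone), and housekeeping genes 1 higher and 1 lower of 16. Stomach genes had 1 higher and 1 lower of 7 (1 and 2 adjusted over the list alone), pancreas acinar genes 1 higher of 4, endothelial genes 1 lower of 3 (1 and 1 adjusted over the list alone) and nerve or glia genes 1 higher of 2. None of 3 mesenchyme genes and not the 1 tested red blood cell gene was called. In villus against ISC, antimicrobial or MHC class II genes had 12 higher in villus and 3 higher in ISC of 22, p53 targets 7 and 8 of 20, developmental transcription factors 9 and 8 of 22, and secreted signals 7 and 6 of 16. Fetal intestine genes had 4 and 5 of 13, sterol synthesis genes 8 and 2 of 22 (8 and 1 adjusted over the list alone), stomach genes 3 and 4 of 8, and imprinted genes 3 and 2 of 17. Housekeeping genes had 5 and 5 of 15, CDK inhibitors 2 and 1 of 6, Hox genes 0 and 3 of 6, endothelial genes 2 and 1 of 3, mesenchyme genes 0 and 1 of 3 and nerve or glia genes 0 and 2 of 4. Where no other count is given, the count adjusted over the list alone was the same, and none of these lists passed Fisher's exact test in either direction (smallest adjusted p = 0.0753).

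PRC2 places a repressive mark, so the design asks whether genes at low levels in wild-type villus were among those that rose. Of 9092 genes below 0.1 RPKM in wild-type villus, 184 were called higher in Eed-null villus, among them Hoxb13, Hoxa10, Nkx6-1, Barx1, Pax3 and Igf2bp1. The mirror count was 4 genes called lower among the 8350 below 0.1 RPKM in Eed-null villus (97.9% of the calls in both sets were higher, 95% exact binomial interval 94.6% to 99.4%). In the class listed at 0 in wild-type villus, 19 of 57 tested genes were called higher, more often than in the other classes pooled (odds ratio 5.93, p = 3.36e-08, Fisher's exact test). In the class above 0 to 0.1 RPKM it was 165 of 200 tested genes. Of all genes in the class from 0.1 to 1 RPKM, 11.1% were called higher and 0.586% lower. Above 10 RPKM 3.07% were called higher (95% exact binomial interval 2.62% to 3.58%) and 5.22% lower (4.63% to 5.86%). Classes set on 1 side of the ratio favour lower calls at the top, and classed by the mean of both groups, genes above 10 RPKM were called higher in 4.32% (3.78% to 4.91%) and lower in 4.80% (4.23% to 5.42%). Every tested gene reached 0.351 RPKM in 1 group, so genes below that level in wild-type villus were tested only if higher in Eed-null villus and could not be called lower. The shares of tested genes in the 2 lowest classes therefore depend on the outcome, and with 1 RPKM required in a group the class at 0 no longer differed (odds ratio 1.63, p = 0.322, Fisher's exact test), with 56 genes left of the 184. A listed 0 may also be a failed estimate. Of 42 tested genes at 0 in 1 group and at 10 RPKM or more in the other, 0 were called. How many of them lie in the class at 0 in wild-type villus was not counted, and they could lower both odds ratios. The intervals treat genes as independent, which they are not.

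**Figure D4:**
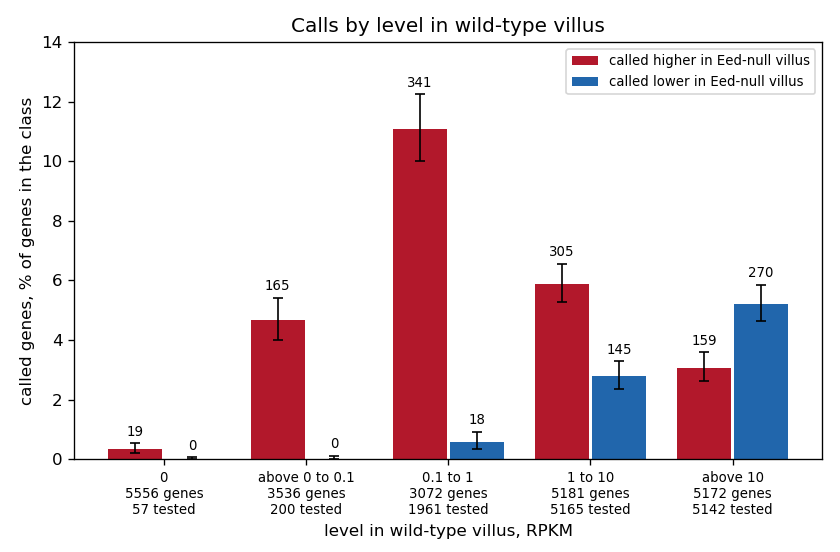
Share of all genes in each class of wild-type villus level (horizontal axis, RPKM) that was called higher (red) or lower (blue) in Eed-null villus, in percent, with 95% exact binomial intervals and the number of called genes above each bar. Below 0.1 RPKM 184 genes were called higher and none could be called lower, since no such gene was tested unless higher in Eed-null villus; above 10 RPKM 159 were called higher and 270 lower.

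The 2 comparisons were set side by side to ask whether genes changed by Eed loss also distinguish villus from ISC. Genes that fell in Eed-null villus were often villus-enriched ones such as Akp3, Fabp6, Reg3a, Plb1 and Dnase1. Among 12098 genes tested in both tables, 249 were called higher in villus than ISC and lower in Eed-null villus, against 142 for independent lists (odds ratio 2.91, adjusted p = 1.58e-26, Fisher's exact test). Only 81 of the genes that fell were ISC-enriched, against 131 for independent lists (odds ratio 0.519, adjusted p = 6.73e-08, Fisher's exact test). Examples were Olfm4, Defa21, Prelp and Adck3. The expected counts were not matched on expression. Lower calls made up 5.22% of genes above 10 RPKM in wild-type villus, 2.80% at 1 to 10 RPKM and 0.586% at 0.1 to 1 RPKM. Genes higher in villus than ISC are selected on the same wild-type villus values, so level alone may give part of this excess and deficit. Genes that rose in Eed-null villus were ISC-enriched in 257 cases, against 229 for independent lists (odds ratio 1.20, adjusted p = 0.0293, Fisher's exact test), among them Psrc1, Gdf15, Mgmt, Rasd1 and Cd44. Dnase1, Adck3 and Rasd1 share locus entries with other genes. The genes that rose were villus-enriched in 246 cases, against 247 (odds ratio 0.992, adjusted p = 0.936, Fisher's exact test), among them Npl, Mbl2, Nt5e, Ada and Sval1. The ISC-enriched excess did not pass with 1 RPKM required in a group (odds ratio 1.19, adjusted p = 0.0892) and was larger with a minimum of 2-fold (odds ratio 1.83, adjusted p = 1.26e-10, Fisher's exact test). Genes below 0.246 RPKM in wild-type villus were tested in both comparisons only if higher in ISC and in Eed-null villus. This filter favours that pair of directions, so it may give part or all of the excess, also at 2-fold.

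Both tables use the same wild-type villus libraries, whose chance values enter both comparisons with opposite sign. Unchanged groups simulated against these libraries gave 0 shared calls in each pair of directions, a value that leaves out all effects and so sets no bound for genes that did change. Part of the excess may come from the shared controls, which cannot be split with 1 value per group. The covariance of the 2 log2 ratios over 8686 genes alone in their locus entry was -0.067 (95% bootstrap interval -0.103 to -0.031), and the simulated covariance was -0.066. Over all 10556 genes with an implied standard error, these were -0.070 and -0.667, and the restriction was chosen after that value was seen. Over 6863 genes alone in their locus entry and with 1 RPKM or more in every group, the covariance was 0.014 (0.0017 to 0.026) and the simulated one -0.046. Spearman's rank correlations of the 2 ratios over these gene sets, in the same order, were 0.034, 0.031 and 0.093. They were weakly positive throughout, so the negative covariances do not describe the ranks of the genes. The simulation takes the standard errors implied by the p-values of the authors' deposited tables. Of the 989 genes called higher in Eed-null villus, 235 were not tested between villus and ISC, and of the 433 called lower, 1 was not.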

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

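The tests here of regression of low values, of scaling and of Cre activity were chosen only after the result was seen. The authors' deposited table marks 91 genes as not tested that were higher in Eed-null villus and whose deposited p passed a Benjamini-Hochberg adjustment over all entries, a signal in data that the comparisons did not use. They include Notch3 at 0.337 against 0.0440 RPKM, Plagl1 at 0.328 against 0.00652 RPKM, and Hoxc13, Hoxd13 and Pax2, each listed at 0 in wild-type villus, in the authors' deposited table. In the opposite direction 1 such gene was found, Slc14a1.

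Genes low in wild-type villus were called higher in Eed-null villus far more often than the reverse. Regression of low values would raise and lower low genes alike, but the count of higher calls below 0.1 RPKM was 46 times the mirror count of lower calls, which argues against it as the whole cause. The authors' scaling between libraries would move all genes by 1 common factor, and the median log2 ratio of -0.10 over expressed genes shows no rise, which argues against it. Cre activity in the Eed-null mice only stays open, since 0 villus RNA groups had active Cre and intact Eed. Loss of PRC2 repression, which the design names, may account for the pattern and remains a hypothesis not told apart from Cre activity, and H3K27me3 data were not analysed here.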

How the results depend on the processing

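Restricting to genes alone in their locus entry, the random matched lists, the split of lists by wild-type villus level and the mirror count of genes lost from low levels were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the tables give 1 value per group, and leaving out libraries and refits were not run for the same reason. Of the values that answer a comparison, 76 alternatives kept their side of the threshold (counts within 1.5 times), 11 counts moved further and 2 tests no longer passed. No result past its threshold reversed. The 76 include 1 entry per symbol, which repeats the main calls, and recentring, which could hardly change them. The overlap of villus-higher and Eed-null-higher genes, with an odds ratio of 0.992, lay between 1.00 and 1.14 under its alternatives and passed under none. Requiring a difference of 1 in log2(RPKM + 1) left 2540 genes higher in villus, 2395 higher in ISC, 378 higher and 128 lower in Eed-null villus, a filter that by construction removes low genes. A q of 0.01 left 258 and a minimum of 2-fold 216 genes lower in Eed-null villus, against 433. At q of 0.1, 7 lists instead of 4 were enriched among genes higher in ISC, and the cause was not tested. With 1 RPKM required in a group, the overlap of ISC-higher and Eed-null-higher genes had an odds ratio of 1.19 (adjusted p = 0.0892), the class at 0 RPKM an odds ratio of 1.63 (p = 0.322, both Fisher's exact test), and 56 genes below 0.1 RPKM in wild-type villus were called higher; fewer genes enter under this filter. The mirror count of genes below 0.1 RPKM in Eed-null villus called lower was 4. Among results for lists enriched at the main setting and for named genes, 1028 alternatives kept their direction and call, 14 lost the call and 2 reversed. Outside the split by level, 4 lost it: goblet cell (adjusted p = 0.207) and sterol synthesis (0.165) with a 2-fold minimum, and secreted signal (0.0542) and imprinted (0.0512) with 1 RPKM required, all by Fisher's exact test. Genes below 0.351 RPKM in wild-type villus are tested only if higher in Eed-null villus. Of 11 lists enriched among genes that rose, 6 remained at or above that level and 1, developmental factors, below it. Hox, CDK inhibitor, secreted signal and imprinted lists passed in neither part. All 15 tested Hox genes lay below that level, where about 50% of other tested genes were called higher. The CDK inhibitor list loses Cdkn2a, just below that level, from its upper part. The 2 reversed were enteroendocrine and interferon lists below that level, with 2 and 1 members. Genes alone in their locus entry gave 3483, 3639, 894 and 405 calls in the order above. Depth per library is unknown, so how far it limits low genes cannot be given.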

Other observations

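The gene families, the added lists, the neighbour tests and all tests of explanations here were chosen only after the result was seen, except the comparison of p53 targets with ISC. Genes sharing a symbol stem were tested over 383 stems for Eed loss and 401 for villus against ISC, with Fisher's exact test and Benjamini-Hochberg adjustment. In Eed-null villus, cytochrome P450 genes (Cyp) went both ways: 12 of 49 fell (adjusted exact p = 5.54e-05), among them Cyp4f40 and Cyp1a1, and 13 rose (adjusted p = 0.0118), among them Cyp4f17, Cyp26b1 and Cyp2c55. Of 12 tested hydroxysteroid dehydrogenase genes (Hsd) 5 fell (adjusted exact p = 0.00599), and of 5 alcohol dehydrogenase genes (Adh) Adh1, Adh4 and Adh7 fell (adjusted p = 0.0426). All 5 tested Hoxb genes rose (adjusted exact p = 0.00116 against all tested genes). They lay below 0.351 RPKM in wild-type villus, where genes were tested only if higher in Eed-null villus. About 50% of other tested genes below that level were called higher, so this p overstates the enrichment. In ISC, 19 of 21 nucleoporin genes (Nup, adjusted exact p = 4.66e-06) and all 6 chaperonin genes (Cct, adjusted p = 0.0227) were higher. So were 32 of 52 genes with the stem Eif (adjusted exact p = 0.000884), among them translation initiation factor genes such as Eif3a. In villus, 142 of 258 solute carriers (Slc, adjusted exact p = 7.07e-14) and all 10 Chmp genes of membrane sorting (adjusted p = 0.000433) were higher. So were 17 of 22 genes with the stem Cox (adjusted exact p = 0.000476), among them cytochrome oxidase genes such as Cox5a.

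Among genes with a regional pattern along the gut, the ileal genes Fabp6 and Slc10a2 fell, while the proximal gene Pdx1 and the posterior gene Hoxb13 rose. Other proximal genes were not set beside Pdx1, so no shift along the gut can be read from these genes. The ileum or colon list had 4 called higher and 4 lower of 15. Whether the position sampled along the gut differed between the groups was not tested. Fabp6 and Slc10a2, of ileal bile acid uptake, had 1444 and 23.9 RPKM in wild-type villus that the labels call proximal, and 251 and 8.65 RPKM in Eed-null villus in the authors' deposited table. Pdx1, a factor of the proximal gut and pancreas, had 20.3 RPKM in Eed-null and 9.46 RPKM in wild-type villus in the authors' deposited table, and was called higher.

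p53 targets were higher in Eed-null villus in 17 of 20 cases. The authors' scaling between libraries is argued against by the list's median log2 ratio of 1.94 (interquartile range 1.66). More ISC in the Eed-null preparations could not lift a gene above both wild-type villus and ISC. On a common scale, all but 2 of the 17 called targets stood above both, such as Cdkn1a at 633 against 160 and 17.7 RPKM. These levels argue against more ISC as the cause for those targets. Other crypt cells were not measured and stay open: the median difference of proliferation genes was -0.32 in log2(RPKM + 1), with 32 of 35 members lower, but that of the stem cell list was 0.13, above 99.17% of matched random lists, and proliferation genes could also fall with the rise of Cdkn2a and Cdkn1a. Cre activity in the Eed-null mice only stays open: 2 of the 17 called targets, Aen and Bbc3, were at or above the Eed-null level in ISC, but the cell type differs and no villus group had Cre with intact Eed. A response to Arf made from Cdkn2a may be another explanation and was not tested.

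Immediate early genes were higher in ISC than in villus in 21 of 31 cases and lower in 4, Dusp6, Klf4, Klf6 and Socs3, a list made after Egr1, Nr4a1 and Fosb were seen among the top genes, so no p is given. Fos had 312 against 98.7 RPKM and Jun 218 against 31.6 RPKM in the authors' deposited table. The authors' scaling between libraries is argued against by the list's median log2 ratio of -2.78 (interquartile range 4.25). Dissociation and sorting of ISC only may account for it and stays open, since 0 groups hold sorted and unsorted cells of 1 type, and a difference between the cell types was not tested. The same list was called higher in Eed-null villus, where neither group was sorted, in 10 of 27 cases and lower in 0. The list was made from a comparison that shares its wild-type villus libraries, whose low values would raise it here too. No p is therefore given, and the count does not bear on sorting. Chaperone genes, a list also made after the data were seen, were higher in ISC in 9 of 14 cases, against 32.3% of all tested genes. No p is given for them either, and none was called in Eed-null villus.

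Neighbouring genes may change together in Eed-null villus. Over 10371 genes, neighbours within 100 kb with unlike symbols were both called higher in 66 pairs, against 49.0 (36 to 62) in shuffles within expression classes (permutation p = 0.0071), among them Commd3 with Bmi1 and Mtap with Cdkn2a. Both were called lower in 23 pairs, against 11.2 (5 to 18, permutation p = 0.001). With pairs of like symbols included, such as Gsdmc2 with Gsdmc3, the counts were 94 against 54.4 and 40 against 11.8, each with permutation p = 0.0001, the smallest these shuffles can give. Pairs with unlike symbols still hold related genes, such as Daf2 with Cd55 and Ereg with Areg, so gene families were not excluded, nor were reads shared between overlapping or related neighbours.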
